A study of Mus musculus with 7 samples.

How the data were processed

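Total RNA from mouse prostate was extracted with TRIzol and made into libraries with a VAHTS Universal kit, per the labels' protocols. The 7 libraries fell into 2 groups by the treatment in the labels, 3 with vehicle and 4 with LIT-927. The submitters' processing notes name fastp, HISAT2, HTSeq and the mouse build mm10. Their versions, roles and settings, the gene annotation, the strand setting and any filter on genes are not given in the sources used here.

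The deposited values are FPKM, fragments per kilobase of gene and per 1000000 fragments of the library, as computed by the authors. The file headers say only that the values are expression, so the unit was worked out from the values. Low values of a gene are whole multiples of a step that depends on the gene and differs between libraries by a constant factor, and values multiplied by annotated transcript length sum to nearly the same total in each library. The plain sums differ, from 445417 to 816215. FPKM are relative to the whole library, so a library in which a few secretory genes take most fragments shows lower values for all others: the 10 most abundant genes took 22.2% to 72.3% of the FPKM of a library. The files list 16019 genes by symbol, with no mitochondrially encoded gene, so a list of these transcripts could not be tested. Of the symbols, 15571 were matched to GENCODE M21, whose build equals mm10, and coordinates come from it.

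Whole fragments were recovered from the steps for all 16019 genes, within 0.01 fragments, and summed to 33585731, 33770241 and 35240765 in vehicle replicates 1, 3 and 4 and to 32595023, 32598219, 32023785 and 34774982 in LIT-927 replicates 1 to 4. They served to state depth and for alternatives. Depth was thus even, and a gene at 0.1 FPKM rests on few fragments. No pair of libraries held identical values above 0.

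A count model had been chosen before the data were examined. The files hold no counts, so the test named for that case was used: limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a mean-variance trend, all 7 libraries, no covariate, no filter and FPKM as deposited. Differences are LIT-927 minus vehicle on the log2(FPKM + 1) scale, which understates the change of low genes. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Means and SDs are of FPKM unless said to be of scores.

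Gene lists for cell types and pathways, 38 in all, were fixed before the data were examined, and 37 had at least 5 measured members. They were tested with camera (limma) at a preset correlation of 0.01, with an estimated correlation and with fry as alternatives. Exact permutation tests are two-sided over the 35 divisions of 7 libraries into 3 and 4, so the smallest p they can give is 0.0286. The immune and stromal scores were put together after list results were seen.

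Named genes followed a rule: always Cxcl12, Cxcr4, Ackr3, Pparg, Fads1 and Fads2; up to 12 genes per direction past the threshold; up to 4 members past the threshold of each called list; and, where no gene passed, the 5 smallest p in each direction. As no gene passed, the members given as examples of a list were chosen after values were seen, from the smallest p in the list's direction, and other genes so chosen are named as such where they appear, apart from the markers of tissue make-up, which were also chosen after values were seen.

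The code was tested on simulated data made from these libraries. Of 200 genes changed among 16019, 0% were recovered at a log2 change of 1, 62.5% at 2 and 86% at 3, with 0, 8 and 15 unchanged genes called. Of lists of 20 genes moved by 1, 5 of 5 were called, and 0 of 35 unmoved lists. Genes were simulated independently of each other, while the estimated correlation within the real lists reached 0.917 (endothelium). The simulation therefore cannot tell how often camera with the preset correlation calls real lists falsely. Alternatives were a pseudocount of 0.1, a minimum of 1 FPKM in 3 libraries, median-of-ratios and upper-quartile scaling, voom on recovered fragments with and without quality weights, library weights, a fold threshold, a replicate block, and leaving out each library or both libraries with high uroplakin transcripts. Tables and figures were made with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.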

Results

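RNA was sequenced from 7 prostate samples of mice with experimental autoimmune prostatitis, an inflammation of the gland induced by immunisation. Of these, 4 came from mice given LIT-927, a small molecule that binds the chemokine CXCL12 and keeps it from its receptor CXCR4, by intraperitoneal injection at 25 mg/kg per day. The other 3 came from mice given the solvent, methyl-β-cyclodextrin, called vehicle here. Injections lasted 14 days. The deposited values were FPKM for 16019 genes, and the whole fragments recovered from them summed to 32023785 to 35240765 per library. The labels do not state that each library came from a separate animal, so p-values measure the spread between these samples, which may in part be technical.

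The comparison asked what CXCL12 neutralisation did to the inflamed prostate transcriptome, and in particular to the desaturase gene Fads2 and the nuclear receptor gene Pparg, which the series title ties to CXCR4. Chemokine transcripts were lower with LIT-927: 21 of 23 measured chemokine genes had a lower mean, and the list score, the mean log2(FPKM + 1) of its members, was 1.39 ± 0.15 (SD, n = 4) against 2.17 ± 0.17 (SD, n = 3) with vehicle. The chemokine list was called with an estimated correlation (camera adjusted p = 0.0342), but that call held in only 3 of 16 other settings. Markers of T and NK cells were lower in 25 of 25 genes, of which 11 reached 1 FPKM in any library. Markers of dendritic cells were lower in 12 of 12, of which 5 reached it, and genes of MHC class II presentation in 13 of 13. These 3 lists, however, were not called with an estimated correlation (camera adjusted p = 0.147, 0.147 and 0.259). Markers of fibroblasts (25 of 25), endothelium (17 of 17) and basal epithelium (14 of 14) were lower alongside them. These lists were not called with an estimated correlation either (camera adjusted p = 0.50, 0.501 and 0.360). Fads2 and Pparg did not differ beyond the spread between libraries, and no gene among the 16019 passed the test after adjustment.

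Chemokines fell as a group in the list test (camera with a preset correlation, adjusted p = 1.1e-13), and theirs was the only list call of the main test that held with an estimated correlation (adjusted p = 0.0342 with an estimated correlation). That call held in 3 of 16 other settings, while the score difference of -0.78 stayed between -0.88 and -0.72 without any one library. Every LIT-927 library scored below every vehicle library for this list. Ccl2, which attracts monocytes, was at 0.469 ± 0.118 FPKM (SD, n = 4) with LIT-927 and 1.80 ± 0.94 FPKM (SD, n = 3) with vehicle. Cxcl9, an interferon-induced attractant of T cells, was at 0.865 ± 0.536 against 5.35 ± 3.84 FPKM. Ccl5, chosen after its values were seen, was at 4.0 ± 3.4 against 12.4 ± 10.4 FPKM, with overlapping groups. No chemokine passed a threshold of 0.05 on its own, either over all genes or adjusted over the list alone, where the smallest adjusted p in limma was 0.0678.

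T and NK cell markers fell as a list (camera adjusted p = 1.0e-17; adjusted p = 0.147 with an estimated correlation). Their score was 0.279 ± 0.087 with LIT-927 and 0.668 ± 0.250 with vehicle, a difference of -0.39 that was -0.25 without vehicle replicate 4. In this list 1 member, Zap70, a kinase of T cell receptor signalling, passed when adjusted over the list alone (limma adjusted p = 0.0457). Zap70 was at 0.0990 ± 0.0574 against 0.390 ± 0.109 FPKM and Cd3e, a subunit of the T cell receptor complex, at 0.196 ± 0.087 against 0.909 ± 0.465 FPKM. These are low levels, resting on 5 to 14 recovered fragments of Cd3e per LIT-927 library and 22 to 71 per vehicle library. Dendritic cell markers fell as a list too (camera adjusted p = 8.0e-10; adjusted p = 0.147 with an estimated correlation), with scores of 0.896 ± 0.059 and 1.25 ± 0.20. Batf3, a transcription factor of cross-presenting dendritic cells, was at 0.491 ± 0.297 against 1.58 ± 0.77 FPKM.

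MHC class II genes fell as a list (camera adjusted p = 2.4e-13; adjusted p = 0.259 with an estimated correlation). Cd74, the invariant chain and also a receptor subunit for MIF, was at 76.2 ± 28.3 FPKM with LIT-927 and 272 ± 153 FPKM with vehicle, and H2-Aa was at 29.5 ± 10.4 against 92.6 ± 45.3 FPKM. Macrophage and monocyte markers were lower in 21 of 24 genes (camera adjusted p = 2.4e-13; adjusted p = 0.360 with an estimated correlation). Among these Lyz2, lysozyme, was at 43.7 ± 21.2 against 131 ± 68 FPKM. Interferon response genes were lower in 22 of 23 (camera adjusted p = 4.3e-07; adjusted p = 0.147 with an estimated correlation), with Gbp2 at 3.79 ± 1.54 against 12.7 ± 5.8 FPKM. The interferon call was lost without vehicle replicate 4 (score difference -0.45, from -0.48), and the macrophage difference went from -0.70 to -0.41 without vehicle replicate 1. Ptprc, the pan-leukocyte marker CD45, was chosen after its values were seen and stood at 0.817 ± 0.313 against 2.40 ± 0.98 FPKM.

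Neutrophil markers fell as a list (camera adjusted p = 3.8e-09, and 0.129 with an estimated correlation), with 10 of 12 members lower and 5 passing when adjusted over the list alone. That adjustment leaves the other lists out of account. Over all genes 0 members passed, and 4 of the 12 reached 1 FPKM in any library. Ngp, a neutrophil granule protein, had the smallest p of all genes and was at 0.0258 ± 0.0298 FPKM with LIT-927 against 0.471 ± 0.124 FPKM with vehicle. It rested on 0 to 2 recovered fragments per LIT-927 library and 14 to 23 per vehicle library. S100a9, a calprotectin subunit, was at 0.475 ± 0.580 against 2.98 ± 0.77 FPKM. The list score was 0.660 ± 0.370 against 0.917 ± 0.070, and LIT-927 replicate 3 set most of that difference: it scored 0.106, the other LIT-927 libraries 0.821 to 0.878, and without it the difference went from -0.26 to -0.07. Inflammatory cytokines were lower in 15 of 20 genes (adjusted p = 0.360 with an estimated correlation), mast cell and eosinophil markers in 7 of 9 (adjusted p = 0.584 with an estimated correlation), and both lists passed camera with the preset correlation, while their score differences shrank to -0.02 without LIT-927 replicate 3 and to -0.08 without vehicle replicate 1 respectively. Without vehicle replicate 4 both calls were lost although the differences grew, from -0.19 to -0.21 for cytokines and from -0.33 to -0.49 for mast cells and eosinophils. The latter call was also lost without vehicle replicate 1 and without LIT-927 replicate 3 (-0.26). B and plasma cell markers did not pass (camera adjusted p = 0.251).

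**Figure D1:**
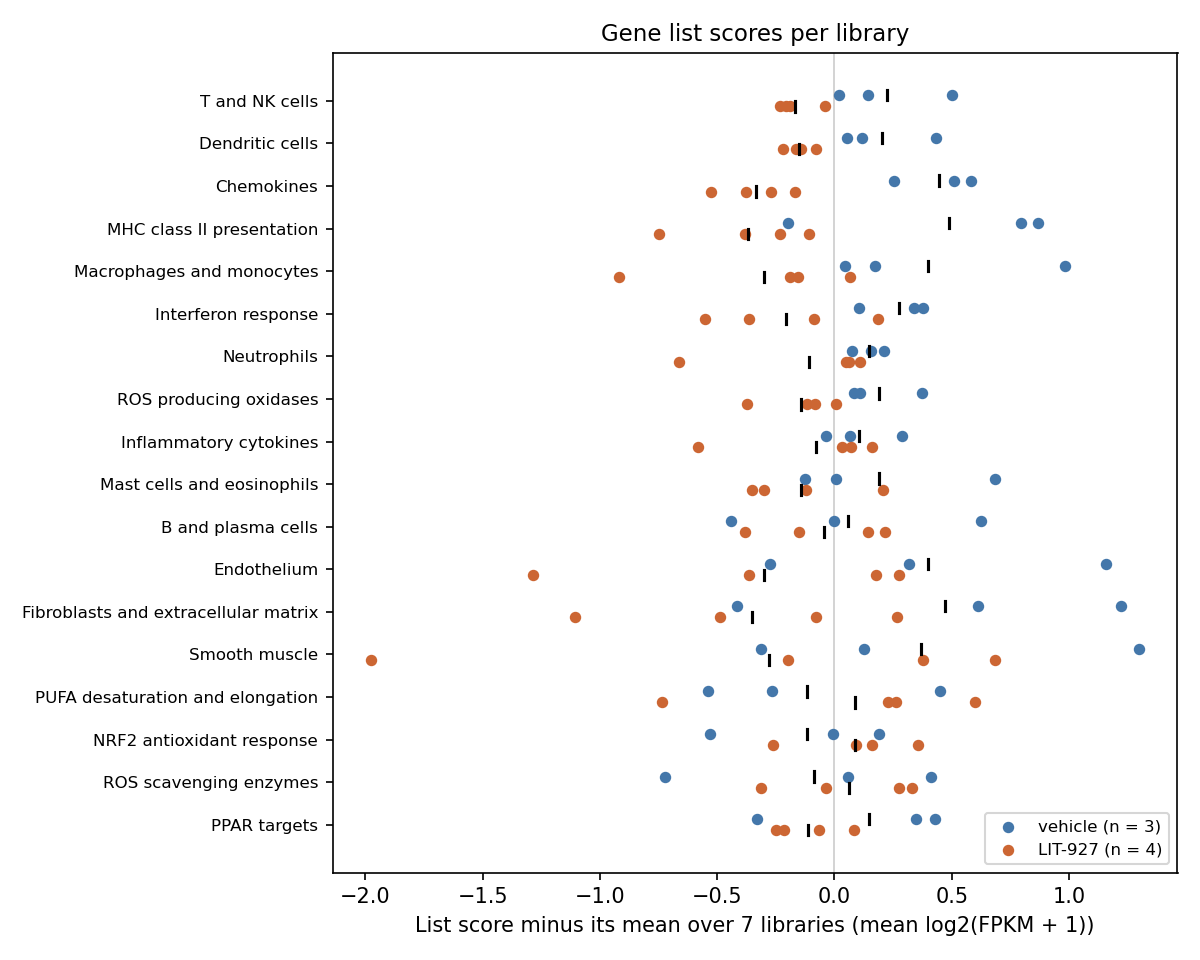
List scores per library, in mean log2(FPKM + 1), each minus its mean over the 7 libraries; points are libraries (vehicle, n = 3; LIT-927, n = 4) and black bars are group means. The groups do not overlap for T and NK cells, dendritic cells, chemokines or ROS producing oxidases, and they overlap for PUFA desaturation and PPAR targets.

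Markers of other cell types in the tissue moved in the same direction. Fibroblast and extracellular matrix genes were lower in 25 of 25 (adjusted p = 0.50 with an estimated correlation), endothelial genes in 17 of 17 (adjusted p = 0.501 with an estimated correlation), smooth muscle genes in 15 of 16 (adjusted p = 0.631 with an estimated correlation) and basal epithelial genes in 14 of 14 (adjusted p = 0.360 with an estimated correlation). Skeletal muscle (adjusted p = 0.501 with an estimated correlation), neurons and Schwann cells (adjusted p = 0.436 with an estimated correlation), erythrocytes (adjusted p = 0.243 with an estimated correlation), adipocytes (adjusted p = 0.617 with an estimated correlation) and immediate early genes (adjusted p = 0.631 with an estimated correlation) were also among the 20 lists lower by camera with the preset correlation. The skeletal muscle difference of -1.17 rested on vehicle replicate 3 and was -0.10 without it, no longer past the threshold. That of smooth muscle went from -0.65 to -0.08 without LIT-927 replicate 3, also no longer past it, and that of immediate early genes from -0.21 to -0.04 without vehicle replicate 1. Without vehicle replicate 1 the smooth muscle difference was -0.18. Without vehicle replicate 4 the smooth muscle and erythrocyte calls were lost although the differences grew, to -0.99 and from -1.02 to -1.09. The adipocyte call was lost without vehicle replicate 3 (-0.14, from -0.30) and without LIT-927 replicate 1 (-0.27). The adipocyte and immediate early differences grew to -0.57 and -0.41 without vehicle replicate 4. Without vehicle replicate 1, the difference went from -0.82 to -0.45 for fibroblasts, from -0.70 to -0.32 for endothelium and from -0.995 to -0.39 for neurons and Schwann cells. Without vehicle replicate 4 these differences were -1.27, -1.04 and -1.65. A stromal score over fibroblast, endothelial and smooth muscle genes was 3.31 ± 0.79 with LIT-927 and 4.05 ± 0.79 with vehicle (exact permutation p = 0.314, two-sided, n = 4 and 3). The stromal difference of -0.74 was -0.34 without vehicle replicate 1, -0.38 without LIT-927 replicate 3 and -1.12 without vehicle replicate 4. The median-of-ratios scaling factors of vehicle replicates 1 and 4 were 1.266 and 0.665, so their deposited values lie high and low for most genes. Score differences without either library, here and for other lists, therefore carry a shift of the whole library.

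The receptor gene Cxcr4 (mm10 chromosome 1, 128588199 to 128592293, minus strand) was at 0.372 ± 0.232 FPKM with LIT-927 and 0.951 ± 0.519 FPKM with vehicle. The difference in log2(FPKM + 1) was -0.49 (SE 0.21; limma adjusted p = 0.998; exact permutation p = 0.143). Its ligand gene Cxcl12 (chromosome 6, 117168535 to 117181367, plus strand) was at 8.74 ± 4.25 against 13.4 ± 7.1 FPKM, a difference of -0.59 (SE 0.56). Ackr3, which encodes the other CXCL12 receptor (chromosome 1, 90203980 to 90216751, plus strand), was at 3.87 ± 2.87 against 9.62 ± 6.55 FPKM, a difference of -1.10 (SE 0.62). The list of the CXCL12-CXCR4 axis was lower in 11 of 14 genes (camera adjusted p = 5.4e-04; adjusted p = 0.501 with an estimated correlation), and its score difference of -0.38 was -0.19 without vehicle replicate 1. Rgs1, a regulator of G protein signalling in leukocytes, was its only member that passed when adjusted over the list alone (limma adjusted p = 0.0474), at 0.553 ± 0.149 against 1.38 ± 0.33 FPKM. The median difference over the axis list was -0.21, and its member Cd74 (-1.69) is also counted in the MHC class II list.

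Fads2, the delta-6 desaturase of polyunsaturated fatty acid synthesis (chromosome 19, 10062765 to 10101746, minus strand), was at 122 ± 101 FPKM with LIT-927 and 59.6 ± 68.0 FPKM with vehicle. The difference in log2(FPKM + 1) was 0.67 (SE 1.49; 95% interval -2.79 to 4.13; exact permutation p = 0.743, n = 4 and 3). Libraries of each group spanned most of the range: vehicle replicates 1, 3 and 4 were at 137, 11.4 and 30.1 FPKM, and LIT-927 replicates 1 to 4 at 250, 128, 2.62 and 107 FPKM. The sign was not stable: the difference was -0.14 without vehicle replicate 3, -0.03 without LIT-927 replicate 1 and 2.01 without LIT-927 replicate 3. Fads1, the neighbouring delta-5 desaturase gene (chromosome 19, 10182888 to 10196877, plus strand), was at 48.6 ± 39.7 against 27.7 ± 29.3 FPKM, a difference of 0.48 (SE 1.22) that turned to -0.03 without vehicle replicate 3 and -0.12 without LIT-927 replicate 1. Pparg (chromosome 6, 115360951 to 115490399, plus strand) was at 0.204 ± 0.266 against 0.480 ± 0.601 FPKM, a difference of -0.25 (SE 0.26; 95% interval -0.85 to 0.36; exact permutation p = 0.486). It became 0.06 without vehicle replicate 3, which held 1.17 FPKM. With a pseudocount of 0.1 the difference was -0.75 for Pparg and -1.19 for Cxcr4, neither past the threshold.

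**Figure D2:**
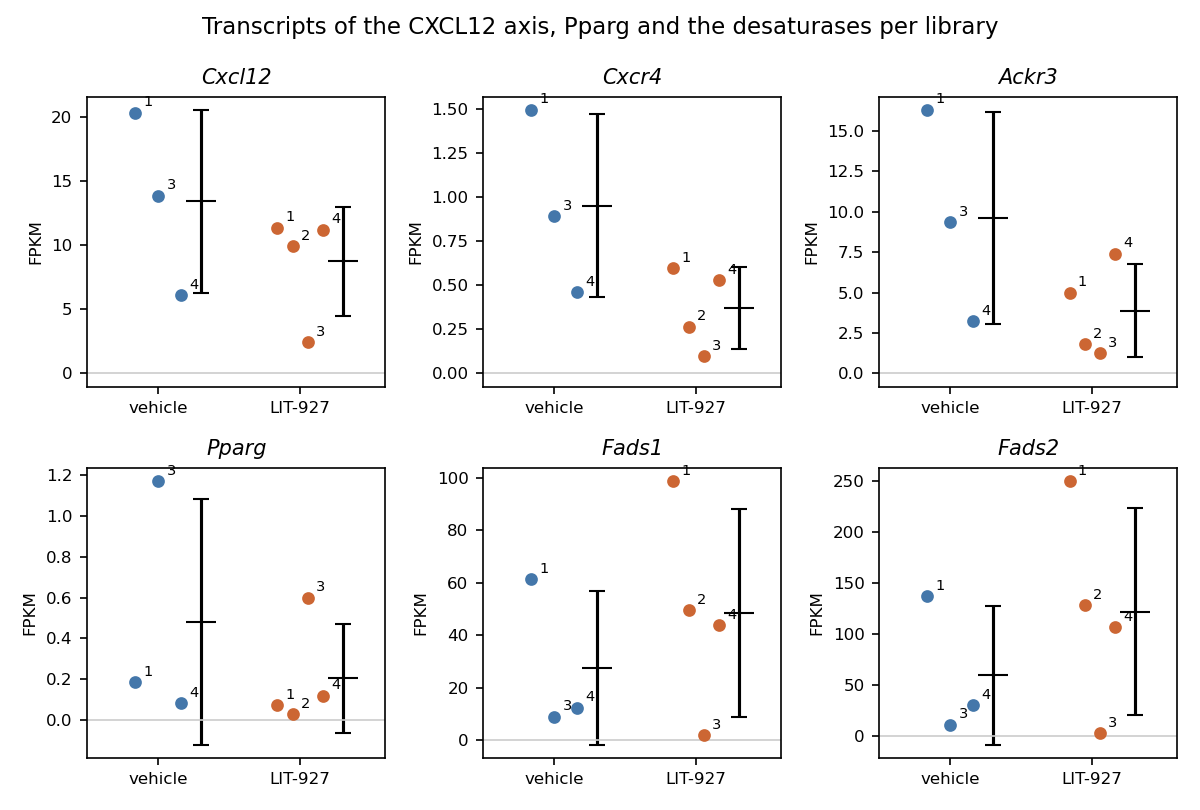
FPKM of 6 genes per library on linear axes, with replicate numbers beside the points and the mean ± SD of each group in black (vehicle, n = 3; LIT-927, n = 4). Fads2 ranges from 11.4 to 137 FPKM among vehicle libraries and from 2.62 to 250 FPKM among LIT-927 libraries.

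The list of PUFA desaturation and elongation genes did not pass the list test (camera adjusted p = 0.251), with 13 of 21 members higher and 8 lower and scores of 3.54 ± 0.57 against 3.34 ± 0.51. Acsl4, which activates arachidonic acid and was chosen after its values were seen, was at 57.7 ± 40.7 against 28.7 ± 23.2 FPKM. It was at 9.19 FPKM in LIT-927 replicate 3, below every vehicle library. Across the 7 libraries it varied with a list of vas deferens and epididymis transcripts (Pearson r = 0.902). That list, described further below, was written after values were seen. PPAR targets did not pass either (camera adjusted p = 0.0900). Of the oxidative stress lists, enzymes that produce reactive oxygen species were lower in 14 of 17 genes (camera adjusted p = 1.9e-06; adjusted p = 0.222 with an estimated correlation). Xdh, xanthine dehydrogenase, was its only member that passed when adjusted over the list alone (limma adjusted p = 0.0301), at 1.09 ± 0.37 against 3.31 ± 0.48 FPKM. The list of these enzymes scored lowest in LIT-927 replicate 3 (0.491), as the macrophage (1.18) and neutrophil lists (0.106) did. Whether it moved apart from leukocyte markers was not tested. NRF2 antioxidant genes were higher in 22 of 28 (camera adjusted p = 0.00902; adjusted p = 0.631 with an estimated correlation) and scavenging enzymes in 18 of 22 (camera adjusted p = 0.0420; adjusted p = 0.719 with an estimated correlation). Prdx1, a peroxiredoxin, was at 339 ± 67 against 212 ± 66 FPKM, while the NRF2 targets Hmox1 and Nqo1, chosen after their values were seen, were at 3.57 ± 0.72 against 4.11 ± 0.78 and 2.58 ± 1.19 against 3.14 ± 1.71 FPKM. Beta-oxidation (20 of 21; adjusted p = 0.631 with an estimated correlation), cholesterol synthesis (21 of 24; adjusted p = 0.652 with an estimated correlation) and nuclear oxidative phosphorylation genes (26 of 28; adjusted p = 0.719 with an estimated correlation) were the remaining lists higher by camera. For all 5 higher lists the score difference was below 0 without vehicle replicate 4, from -0.17 for scavenging enzymes to -0.004 for NRF2 genes. Their calls were lost without vehicle replicate 4 for beta-oxidation, oxidative phosphorylation and scavenging enzymes, without LIT-927 replicate 3 for cholesterol synthesis (0.09, from 0.24) and without LIT-927 replicate 1 or 4 for scavenging enzymes (0.08 and 0.06, from 0.15). The NRF2 call was lost without vehicle replicate 1 although the difference grew from 0.20 to 0.36. Vehicle replicate 4 had the lowest median-of-ratios factor of all libraries (0.665) and vehicle replicate 1 the highest (1.266). Part of the change in these differences without either is thus a shift of the whole library. Differences without each library after scaling were not computed. Ferroptosis, eicosanoid synthesis, fatty acid synthesis, proliferation, unfolded protein response, heat shock, urothelium, seminal vesicle and prostate luminal lists did not pass, with camera adjusted p from 0.0695 to 0.936.

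The make-up of the tissue pieces varied within both groups. Transcripts of seminal vesicle secretion took 12%, 43.5% and 72.4% of all FPKM in vehicle replicates 1, 3 and 4, and 40.3%, 51.1%, 42.7% and 29.4% in LIT-927 replicates 1 to 4. Upk1a, a uroplakin of bladder and urethral lining, was at 172 FPKM in vehicle replicate 3 and 253 FPKM in LIT-927 replicate 3, against at most 10.1 FPKM elsewhere. Akr1b7, known as the mouse vas deferens protein, was at 84.5 and 15.9 FPKM in those libraries and at 1597 to 17099 FPKM in the others. Fads2 was lowest, and Pparg highest, in that same pair of libraries. The pair also scored highest for the prostate luminal list, at 7.22 and 6.42 against 4.34 to 5.28 elsewhere. Of its members, Sbp was at 53139 and 114916 FPKM in the pair (8.0 to 5316 elsewhere) and Msmb at 1020 and 337 FPKM (at most 6.62 elsewhere). Pbsn and Tgm4 were instead highest in vehicle replicate 1. High uroplakin transcripts are therefore not the only mark of this pair. On the first principal component, with 51.2% of the variance, LIT-927 replicate 3 lay farthest out (81.5). Vehicle replicates 3 and 4 lay on the same side (28.6 and 23.8), and the other libraries on the opposite side (-47 to -17).

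**Figure D3:**
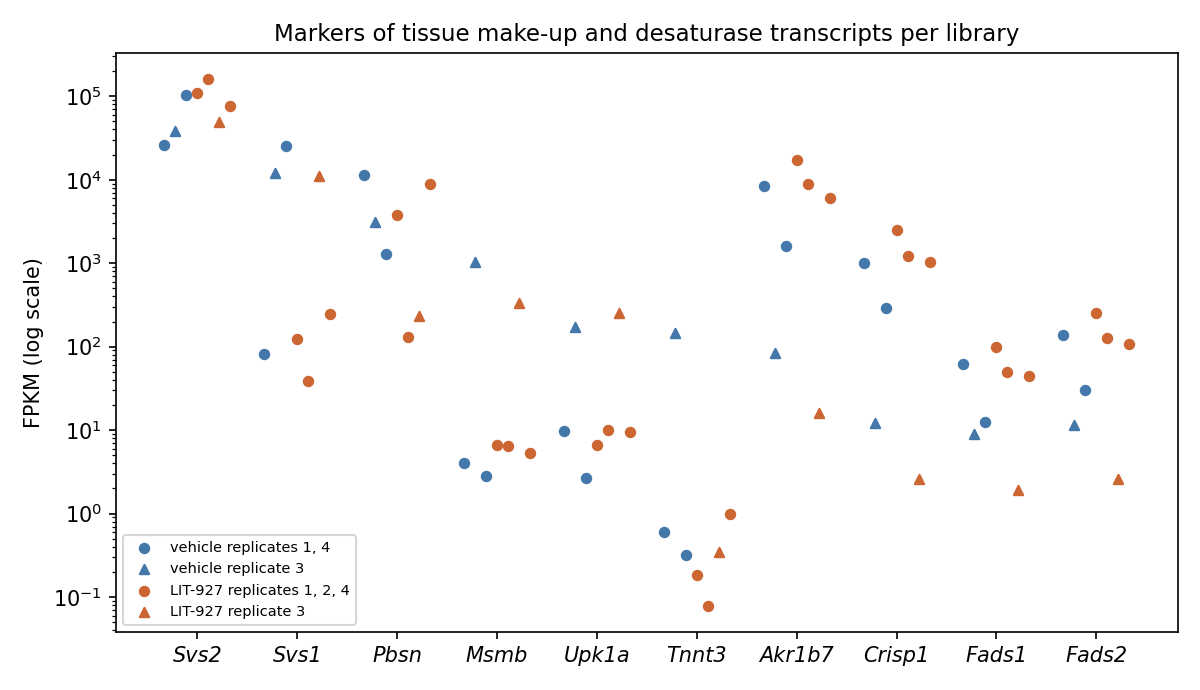
FPKM on a log scale of genes marking different tissues and of the desaturase genes, by library (triangles, replicate 3 of each group; circles, the other replicates). Fads1, Fads2, Akr1b7 and Crisp1 are lowest in the same pair of libraries, in which Upk1a is highest.

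In limma, 0 genes were higher and 0 lower with LIT-927 (smallest adjusted p = 0.998), and voom on recovered fragments also called 0 in each direction, while library weights that did not converge called 2841 higher and 3231 lower. At an unadjusted p under 0.05, 115 genes were higher and 474 lower, where 801 would be reached by chance. These counts were 347 and 951 with median-of-ratios scaling, 384 and 880 with upper-quartile scaling, 242 and 1031 with voom, 824 and 1671 with quality-weighted voom, and 49 and 1285 without vehicle replicate 4. The balance turned to higher genes without LIT-927 replicate 3 (827 and 383), without both uroplakin-high libraries (517 and 428) and, barely, without vehicle replicate 1 (296 and 286). The 5 smallest p-values in each direction belonged to Fgfbp1, Rpl31-ps12, Foxh1, Mfsd6l and Ttc30a2 on the higher side and to Ngp, Stard8, Epb41l3, Garnl3 and Nat8l on the lower side, none past the threshold. Fgfbp1, a carrier protein for fibroblast growth factors, was at 46.9 ± 24.2 FPKM with LIT-927 against 10.4 ± 4.1 FPKM. Rpl31-ps12 is a pseudogene whose reads cannot be told apart with certainty from those of its parent gene. The exact permutation test of the scores gave its smallest possible p, 0.0286, for 3 of 37 lists (adjusted p = 0.353 over the lists), and other divisions of the same 7 libraries into 3 and 4 gave a median of 18 lists by camera with the preset correlation, against 25 here. The chemokine call with an estimated correlation was lost without any one library other than LIT-927 replicate 2 (adjusted p up to 0.445, without vehicle replicate 4), with a pseudocount of 0.1 (adjusted p = 0.0501), with upper-quartile scaling (adjusted p = 0.0508) and in both voom fits (adjusted p = 0.0733 and 0.146). It was also lost with the replicate block (adjusted p = 0.501), with library weights (adjusted p = 0.359) and without both uroplakin-high libraries (adjusted p = 0.186).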

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

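Except for the divisions tested for the counts of lists and the scaling test of Fads2, the tests of explanations here were chosen after the results they address had been seen. Among 135 named genes, lists and library-level measures tested in the 4 LIT-927 libraries, 10 had a library far from the other 3. A rate of 1 in 20 would give 6.8, but genes and lists share members, so that is only a rough guide. In LIT-927 replicate 3, Cxcl12 was lowest at 2.44 FPKM (others from 9.92 to 11.4), Il1a lowest at 0.016, Cd68 lowest at 1.02 (others from 2.72 to 3.01), Elovl5 lowest at 17.9 (others from 30.6 to 33.4) and Ccl5 highest at 9.08 (others from 2.07 to 2.76). The eicosanoid list score (1.53) and the neutrophil list score (0.106) were also lowest in that library. Mpo was at 0.012 FPKM in LIT-927 replicate 2 and Mylk4 at 0.033 in LIT-927 replicate 4, each with the others at 0. The erythrocyte list score was highest in LIT-927 replicate 4, at 3.52.

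Immune transcripts were lower with LIT-927. A score over all 10 immune lists fixed beforehand, 174 genes of which 155 had a lower mean, was 1.28 ± 0.14 (SD, n = 4) against 1.74 ± 0.18 (SD, n = 3). An earlier version over 6 lists picked for their results had a difference of -0.58 and was replaced by the wider score, whose difference is -0.46. Only 1 of 35 divisions, the real one, reached this size (0.461, highest other 0.413), but the score was put together after its lists had been seen lower, so this leaves chance open. Scaling and the uroplakin-high libraries are argued against as whole causes, since the difference was -0.511 after median-of-ratios scaling and -0.465 without vehicle replicate 3 and LIT-927 replicate 3. Less stroma and vessel tissue in the LIT-927 pieces stays open too. Adjusted for the stromal score the difference was -0.338 (exact permutation p = 0.0571), and an effect of LIT-927 on leukocytes cannot be told apart from less stroma here. The erythrocyte list score was also lower (2.57 ± 0.64 against 3.59 ± 0.27), and no adjustment for it was run. LIT-927 replicate 4 lay within the vehicle range for erythrocytes (3.52) but below every vehicle library for the immune score (1.40).

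With 0 genes called, 35 of 35 divisions must give as many, which tests nothing. The highest other, 102 genes, came from setting vehicle replicates 3 and 4 and LIT-927 replicate 3 against the rest, a structure of the samples that crosses the groups. The seminal vesicle list score was 12.3 to 13.2 in those libraries and 8.8 to 9.9 in the rest. Its member Svs1 was at 11062 to 25355 FPKM in them and at 38.8 to 243 FPKM in the rest, while Svs2 did not divide the libraries so. For the 20 lists lower, 2 of 35 divisions gave as many (highest other 23), so chance cannot be excluded at 0.05. For the 5 lists higher, 27 of 35 gave as many (highest other 20).

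Fads2 spread over a 95.5-fold range between libraries. Scaling is argued against, since the range was still 71.2-fold after median-of-ratios scaling. A candidate explanation is vas deferens or epididymis tissue in some pieces. Over a list of such transcripts, 8 measured, log2 Fads2 correlated with the list mean across the 7 libraries (Pearson r = 0.984, Spearman rho = 0.964; exact permutation p = 5.95e-04 and 0.00278, adjusted 0.00268 and 0.00833 over 9 relations), but 4 of the 8 had been seen varying with Fads2 before the list was written, so that value is circular. Over the other 4 members r was 0.928 and rho 0.929 (exact permutation p = 0.00159 and 0.00675, adjusted 0.00286 and 0.0121), and r was 0.965 without the 2 libraries farthest from the median, which rests on Lcn5 (r = 0.924) while Adam28 went the other way (r = -0.562). Levels differed widely within the list: Akr1b7 reached 17099 FPKM, Crisp1 2508, Defb42 580 and Serpina1f 377, all among the 4 seen beforehand, while Lcn5 reached 4.42 and Rnase10 0.105. How many of the listed genes prostate epithelium itself expresses was not tested, though Crisp1 is also in the prostate luminal list and Serpina1f in the seminal vesicle list. The relation held in direction within both groups, no label records such tissue, and a biological difference between animals stays open.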

How the results depend on the processing

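Library weights, voom without quality weights and leaving out both uroplakin-high libraries were chosen after seeing the data. In limma and voom, 0 genes passed in either direction under all settings run except library weights, and apart from that exception the smallest adjusted p of any setting was 0.0649, with median-of-ratios scaling. Library weights called 2841 genes higher and 3231 lower, with Fads2 at 3.47, Pparg at -0.98 and Cxcr4 at -0.38 past the threshold and 1 list higher. They also turned Hmox1 (0.20), Nqo1 (0.033) and Elovl5 (0.14), and the camera direction of cholesterol synthesis (score difference 0.24) and smooth muscle (-0.65). The weights did not converge and gave vehicle replicate 3 a weight of 31.5 against at most 2.26 elsewhere, so these calls rest on nearly 1 vehicle library and are not taken as results.

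Pseudocount 0.1 gave Cxcr4 -1.19 and Pparg -0.75, voom Cxcr4 -1.56 and Pparg -1.42, and voom with quality weights Cxcr4 -1.10, Pparg -2.36 and Fads2 2.12, none past the threshold. Leaving out each library in turn gave Fads2 from -0.14 to 2.01, Pparg from -0.44 to 0.064, Cxcr4 from -0.68 to -0.30, Fads1 from -0.12 to 1.58, Mylk4 from -0.88 to 0.009, Nqo1 from -0.51 to 0.10, Elovl5 from -0.20 to 0.085, 15 to 23 lists lower and 2 to 5 higher (2 without vehicle replicate 4). Without vehicle replicate 3, Fads1 was -0.03, Mylk4 0.009, Fads2 -0.14 and Pparg 0.064; without LIT-927 replicate 1, Fads1 was -0.12 and Fads2 -0.03. Nqo1 was 0.10 without vehicle replicate 1 and 0.088 without LIT-927 replicate 3, when Elovl5 was 0.085. Without both uroplakin-high libraries, Mylk4 was 0.012, Nqo1 0.086, Elovl5 0.044 and 3 lists were higher, as with the 1 FPKM filter. With an estimated correlation 0 lists were higher and 1 lower, likewise with fry. The chemokine adjusted p with an estimated correlation ranged from 0.0221 to 0.501 over 16 settings and was past the threshold in 3 (the 1 FPKM filter, median-of-ratios scaling and without LIT-927 replicate 2); neutrophils also passed with median-of-ratios scaling, and T and NK cells without vehicle replicate 3. The cause was not tested.

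The labels do not say whether replicate numbers pair the samples, and the values leave it unresolved: deviations of same-numbered libraries correlated at 0.58, 0.76 and -0.17, and 1 vehicle library correlated best with its own number. With the replicate block, 0 genes passed, 21 lists were lower and 5 higher with the preset correlation and 0 with an estimated one. There the chemokine list was at camera adjusted p = 0.501, and Fads2 was 0.29, Cxcr4 -0.46 and Pparg -0.18. The vehicle group has no replicate 2, so LIT-927 replicate 2 adds nothing to these gene differences, which equal those without that library. The block thus rests on the same-numbered libraries alone. The planned count-based tools were not run, because the deposited values are FPKM; voom on recovered fragments was run in their place. Of 1461 other values for genes, 1380 kept their direction and side of the threshold. For lists, 356 of 397 kept the camera direction and side of the threshold with the preset correlation. That direction is relative to other genes, so a list can keep it while its score difference changes sign. Without vehicle replicate 4 this was so for cholesterol synthesis (-0.06, from 0.24) and NRF2 genes (-0.004, from 0.20). The estimated correlation and fry are not in this tally.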

Other observations

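Erythrocyte transcripts differed in level between libraries. Hbb-bs, an adult beta-globin, was at 29.2 ± 38.2 FPKM (SD, n = 4) with LIT-927 and 111 ± 38 FPKM (SD, n = 3) with vehicle. LIT-927 replicate 4 held 86.4 FPKM, near the lowest vehicle library (88.4 FPKM), and the other LIT-927 libraries 7.46 to 12.7 FPKM. The erythrocyte list was lower in 8 of 9 genes (camera adjusted p = 4.7e-06; adjusted p = 0.243 with an estimated correlation). Tnnt3, a fast skeletal muscle troponin, was at 147 FPKM in vehicle replicate 3 and at most 1.0 FPKM in the other libraries. Klf2, a transcription factor of endothelium and quiescent T cells, was at 4.67 ± 2.09 against 10.8 ± 2.0 FPKM.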
